A study of Mus musculus with 8 samples.

How the data were processed

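RNA-seq was analysed from sciatic nerves of mice at postnatal days 4, 14, 30 and 60 (P4, P14, P30 and P60). At each age there was 1 control library and 1 library from the Seh1l conditional knockout called Seh1cKO, 8 libraries in all, per the labels. Seh1l encodes a nucleoporin of the Y complex of the nuclear pore that is also part of GATOR2, a regulator of amino acid signalling. Total RNA was extracted with a column kit and sequenced by a standard Illumina protocol, per the labels' protocols. The genome build was mm39, per the submitters' processing notes. The aligner, the counting tool, the annotation, strand handling and the treatment of reads that match several genes are not given in the sources used here.

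The deposited table gives 2 values per gene and library for 19981 genes. The read count columns, named so per the file headers, were taken as estimated counts, since 56.5% of the deposited values were whole within 1e-06. They were rounded to whole numbers before testing, which moved no value by more than 0.5. The other deposited columns, which per the file headers carry no unit, were taken as FPKM from their values, and how gene length was set is not given in the sources used here. They were taken so because their ratio to library-scaled counts lay within 5% of the gene mean for 96.6% of the values of 4927 genes above 10 in all 8 libraries. FPKM entered 1 alternative fit. No row lacked a gene name. The supplied reference annotation was of another build, so no coordinates are given and its synonyms served only to match symbols.

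Library totals were 19206457 to 19766680 estimated counts. At that depth a count of 0 allows up to 3 counts, or 0.152 to 0.156 CPM (counts scaled to the library total), in a library. Ratios within a pair of libraries carry 95% exact binomial intervals where given, and intervals and floors cover counting error only. None of the 28 pairs of libraries held identical values, and correlations of log2 CPM between libraries were 0.861 to 0.978.

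Each genotype-by-age group had 1 library, so no single age has a replicate check and no p-value is given for it. The genotype difference was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in a model of age as a factor plus genotype, with the 4 ages as replicates and 3 residual degrees of freedom. The residual holds both noise and any real change of the genotype difference with age. The labels do not say how many animals gave each library, so p-values measure the spread between these libraries. Another model added genotype by log2 of the day, with 2 residual degrees of freedom. P60 was compared with P4 in the additive model, with the 2 genotypes as replicates. Counts were scaled by TMM and filtered by filterByExpr (minimum count 10, minimum total 15), which kept 15839 genes and left out 4142. Benjamini-Hochberg (BH) values below 0.05 were called. Log2 ratios at a single age were differences of TMM-scaled log2 CPM with a prior count of 2. Ratios not given as log2 were quotients of TMM-scaled CPM without a prior count, and the intervals belong to these. At low counts the log2 ratios therefore lie closer to 0 than the ratios. At single ages, genes were counted and ranked over those with a mean of at least 5 CPM in the pair.

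The 39 gene lists, the tests, most alternative settings and the rule for naming genes were fixed before the data were examined. Of 620 list entries 598 were found, and 37 lists had at least 4 tested genes. The epidermis list had 2 tested genes and the mitochondrially encoded list 0, so neither was tested. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, BH-adjusted over the lists, then with an estimated correlation and with fry. At a single age the median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression.

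The rule names Seh1l, then the 12 highest and 12 lowest fold changes among called genes of at least 5 CPM with 1 sign at all 4 ages, filled by lowest p where a direction had fewer. It adds the 8 highest and 8 lowest ratios at each age, the 8 genes of lowest p for the change with age, the 10 highest and 10 lowest for P60 against P4, and up to 4 members of each list with the largest fold change. Predicted genes are counted but not named, and some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

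The steps were tested on simulated data with 200 changed genes. For the genotype difference, over 15625 genes, 50.7% of 1.5-fold, 88.1% of 2-fold and 98.5% of 4-fold changes were recovered, with 20 false calls beside 34, 59 and 65 true ones. For the change of the genotype difference from P4 to P60, over 15602 genes, 76% of 4-fold and 100% of 16-fold changes were recovered, with 18 false calls. For P60 against P4, over 15617 genes, 11.9% of 1.5-fold, 64.2% of 2-fold and 97% of 4-fold changes were recovered, with 13 false calls. In all 3 comparisons the share of false calls exceeded the nominal BH level of 0.05. Among 36 lists the list raised 1.5-fold was called, and so was 1 list that had not been changed. Genes were drawn independently of each other, so members of simulated lists were not correlated. In the real data the estimated inter-gene correlation was 0.37 for cell cycle genes and 0.971 for cholesterol synthesis genes. The simulation therefore does not give the rate of false list calls in these data.

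Alternatives were RLE size factors, library size only, no filter, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-trend, other age terms, each age pair left out, removal of muscle, blood, adipocyte and epidermis genes before scaling, and other prior counts and minimums for single ages. Chosen after the data were seen were fits with library sex (taken from Ddx3y counts), muscle level or blood level as a term, a fit on the P4 and P30 pairs, and limma on log2(FPKM + 1).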

Results

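The data describe the sciatic nerve transcriptome of control and Seh1cKO mice at P4, P14, P30 and P60. The series title concerns Schwann cells, the glia that myelinate peripheral axons, with genome stability and necroptosis. Each of the 8 groups held 1 library of 19206457 to 19766680 estimated counts, with 17538 to 17997 genes counted.

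Seh1l transcripts fell in Seh1cKO. The mean was 43.3 ± 2.9 CPM in control and 23.3 ± 2.0 CPM in Seh1cKO (SD, n = 4 ages each), or 53.9% of control. The ratio to control was 0.452 at P4 (counting interval 0.403 to 0.507), 0.554 at P14, 0.566 at P30 and 0.596 at P60 (0.533 to 0.666). Across ages the log2 fold change was -0.89 (SE 0.087, BH 0.0335, edgeR quasi-likelihood test). Whole nerve was measured, and reads from undeleted parts of the gene cannot be separated here.

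**Figure D1:**
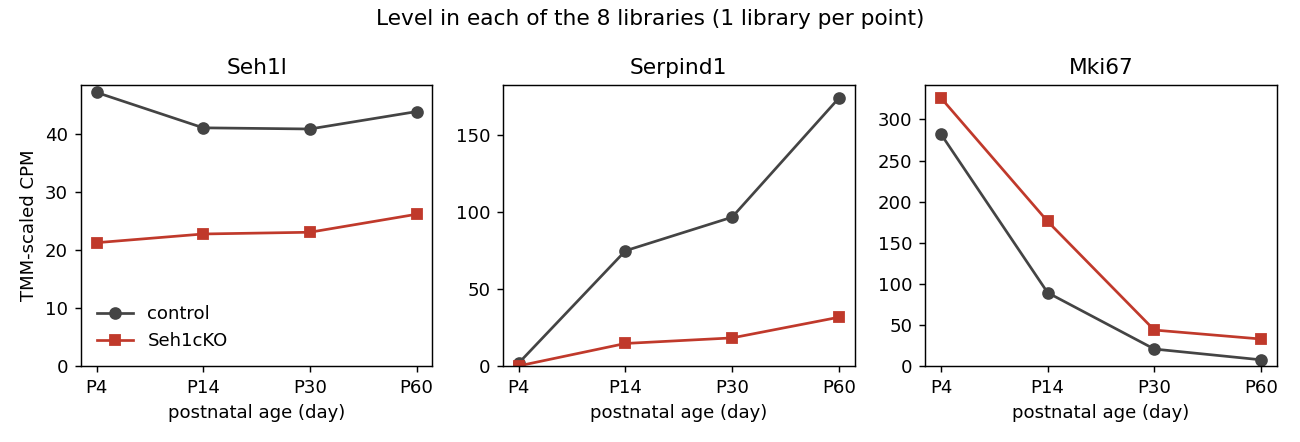
TMM-scaled CPM (vertical axes, from 0) of Seh1l, Serpind1 and Mki67 at 4 evenly spaced ages, with 1 library per point. Seh1l lies at 40.9 to 47.2 CPM in control and at 21.3 to 26.2 CPM in Seh1cKO.

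The libraries also differed in sex-linked transcripts and in tissue composition. The Y-linked gene Ddx3y had 688 counts in Seh1cKO and 1331 in control at P4, and 1067 and 932 at P30. It had 2 counts in Seh1cKO and 677 in control at P14, and 626 in Seh1cKO and 0 in control at P60, so these pairs differed in opposite directions. In the P14 Seh1cKO library the other Y-linked genes Uty, Kdm5d and Eif2s3y, which have X-linked relatives, had 89, 106 and 132 counts, and in the P60 control library 62, 89 and 120. The labels used here do not give sex. Red blood cell genes took 0.763% of counts in Seh1cKO and 0.219% in control at P4, 0.115% and 0.807% at P30, and 3.75% and 1.47% at P60. Skeletal muscle genes took 0.013% in Seh1cKO and 0.126% in control at P4, and 0.0969% and 0.0228% at P30.

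**Figure D2:**
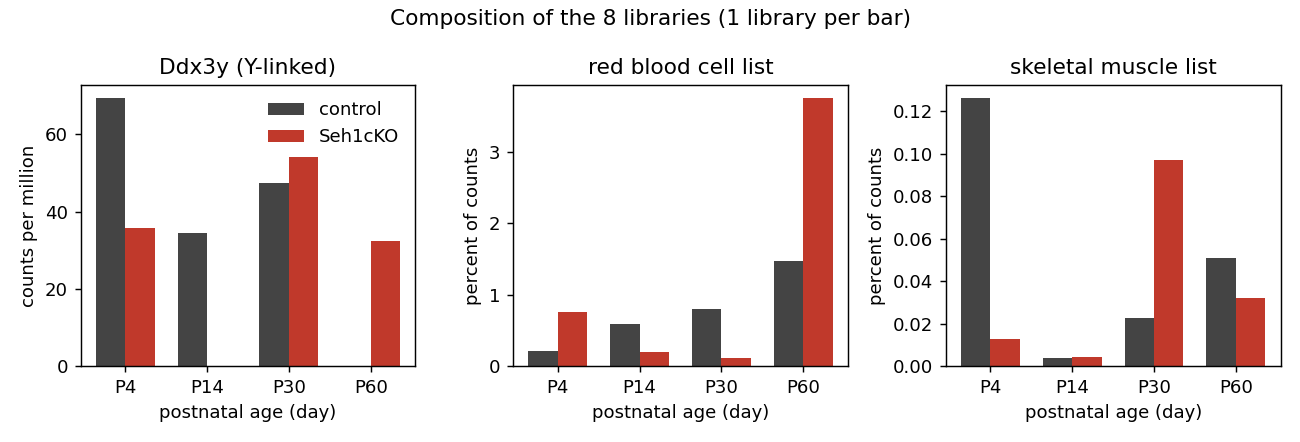
Ddx3y CPM and the percent of all counts in the red blood cell and skeletal muscle lists (vertical axes, from 0) by age, with 1 library per bar. Ddx3y is near 0 in Seh1cKO at P14 and at 0 in control at P60.

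The genotype comparison asked which transcripts differed between Seh1cKO and control across the 4 ages. Serpind1, which encodes the thrombin inhibitor heparin cofactor II, fell to 0.185 of control (log2 fold change -2.43, SE 0.096, BH 0.00128). At P60 it had 174 CPM in control and 31.8 CPM in Seh1cKO. Them5 fell to 0.188 of control, Ttll6 to 0.233, Fads6 to 0.238, Ptpru to 0.40 and Magix to 0.408. Cyp4v3, Pex5l, the collagen gene Col28a1, Shpk and the receptor gene Gpr37l1 fell to between 0.449 and 0.522 of control. Cdc20, an activator of the anaphase-promoting complex, rose 1.99-fold (SE 0.106 on the log2 scale, BH 0.0415). Cip2a rose 1.92-fold and Uhrf1, which maintains DNA methylation through replication, 1.86-fold. Calca, which encodes calcitonin gene-related peptide, rose 1.9-fold. Nav2, Id2, Dusp4, Lrrfip1, Phlda1 and Fign rose 1.42-fold to 1.68-fold. The mitotic genes Knstrn and Racgap1 had folds of 1.79 and 1.68 without passing the threshold (BH 0.0508 and 0.052). BH values are from the edgeR quasi-likelihood test.

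Of 15839 genes 50 were called, 13 higher (1 of them a predicted gene) and 37 lower. All 50 had 1 sign at all 4 ages, which the call itself largely requires, because the ages were the replicates. Over all genes 26.3% had 1 sign at all 4 ages, against 12.5% if signs were independent between ages and equally likely. This share was not compared with that under swapped genotype labels. Among other called genes, chosen after their values were seen, the growth factor gene Bmp7 had a log2 fold change of -0.81, Prkca of -0.89, the ankyrin gene Ank3 of -0.57 and Agrn of -0.52. An unadjusted p below 0.05 was found for 2849 genes. With edgeR the number called was 0 without the P14 pair (1794 genes at an unadjusted p below 0.05), 1 without P30, 3 without P60 and 177 without P4. It was 0 in the P4 and P30 pairs alone (896 at an unadjusted p below 0.05), 3 with library sex (Ddx3y present or absent) as a term and 1 with the blood level as a term, while DESeq2 called 890 and limma-trend 110. With the sex term 2706 genes had an unadjusted p below 0.05. Presence of Ddx3y differed within pairs only at P14 and P60, in opposite directions, so that term is balanced against genotype. It also takes up a residual degree of freedom, so the fall in calls does not show that sex explains them. The muscle level as a term takes up as many, and with it 98 genes were called, 34 of them among the 50. Why calls fell with the sex and blood terms was not tested.

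Cell cycle genes ranked higher in Seh1cKO than other genes. All 30 had a log2 fold change above 0 (median 0.73). EdgeR called 1 of them, Cdc20, over all genes, with 28 at an unadjusted p below 0.05, DESeq2 called 22 and limma-trend 5, and 28 passed when adjusted over the list alone. The mitotic cyclins Ccnb2 and Ccnb1 had log2 fold changes of 1.22 (SE 0.195) and 1.12 (SE 0.191), and Cenpe and Tpx2 of 1.07 and 1.04. The camera BH was 6.2e-17, with adjusted p = 0.457 with an estimated correlation. The list median log2 ratio was 0.44 at P4, 0.74 at P14, 0.43 at P30 and 1.20 at P60, and red blood cell medians at these ages were 1.67, -1.81, -2.66 and 1.63. Mki67, a list member chosen after its values were seen, had ratios of 1.16, 1.97, 2.11 and 4.23.

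Nucleoporins outside the Y complex ranked higher (18 of 20 above 0, median 0.19, camera BH 0.000541, adjusted p = 0.457 with an estimated correlation). Over all genes edgeR called 0 of them, with 10 at an unadjusted p below 0.05, DESeq2 called 1 and limma-trend 1, and 4 passed when adjusted over the list alone. Nup210, Pom121, Nupl2 and Nup93 had log2 fold changes of 0.56, 0.42, 0.31 and 0.30. In the Y complex list, which was not called (10 genes, camera BH 0.291), Seh1l was the 1 called member, and Nup37, Nup43 and Nup98 had 0.57, 0.40 and 0.22. The GATOR2 list, which also holds Seh1l, was not called (5 genes, camera BH 0.207). Mios, Wdr59 and Wdr24 had -0.10, -0.07 and 0.05, and the sign of each turned in an alternative fit.

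Lists of genome stability ranked higher. For 26 DNA damage response and repair genes the median was 0.12 and the camera BH 0.0021, with 23 above 0 (adjusted p = 0.457 with an estimated correlation). Over all genes edgeR called 0, with 6 at an unadjusted p below 0.05, DESeq2 and limma-trend called 0, and 0 passed when adjusted over the list alone. Exo1, Chek1 and Brca1, which act in DNA replication and repair, had log2 fold changes of 0.64, 0.62 and 0.43. For 27 p53 target genes the median was 0.17 and the camera BH 0.0132 (adjusted p = 0.457 with an estimated correlation, and 0.0787 without the P60 pair), and 22 lay above 0. Over all genes edgeR called 1, with 7 at an unadjusted p below 0.05, DESeq2 called 3 and limma-trend 1, and 4 passed as higher and 1 as lower when adjusted over the list alone. Eda2r, a receptor gene, rose (log2 fold change 1.75, SE 0.218, BH 0.0477 by edgeR), with ratios of 3.74, 4.61, 2.40 and 3.16 from P4 to P60. Gdf15, Pmaip1 and Plk2 had 2.25 (SE 0.58), 0.89 and 0.58 and were not called by edgeR, and Plk2 was called by DESeq2. Gdf15 and Pmaip1 had low levels, with means of 0.59 and 0.75 CPM. Of the other p53 targets, chosen after their values were seen, Cdkn1a (mean 483 CPM) had 0.008, Mdm2 0.17 and Sesn1 -0.43.

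Necroptosis and death receptor genes were not called as a list (18 genes, camera BH 0.199), and edgeR called 0 of them, with 3 at an unadjusted p below 0.05, while DESeq2 called 1, limma-trend 0, and 0 passed when adjusted over the list alone. Zbp1, a nucleic acid sensor that can start necroptosis, had a log2 fold change of 1.07 (SE 0.281, BH 0.128 by edgeR). Tnf had 0.99, Tlr3 -0.53 and Ripk3 0.45. Zbp1 passed the threshold in 0 of 17 alternative fits, and Tlr3, which was lower, in 1 of 18. The list median log2 ratio was 0.06 at P4, 0.08 at P14 and 0.06 at P30, within the central 95% of random lists, and 0.26 at P60 (percentile 99.3, 13 of 18 higher). The lists of DNA and RNA sensing (camera BH 0.101) and of apoptosis and pyroptosis effectors (0.339) were not called.

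Chemokine, macrophage, lipid-associated macrophage, interferon-stimulated and MHC class I lists ranked higher, and the other immune lists were not called. All 21 chemokine and cytokine genes had values above 0 (camera BH 0.000771, adjusted p = 0.457 with an estimated correlation). The interferon-induced chemokine gene Cxcl10 had a log2 fold change of 2.07 (SE 0.281, BH 0.0522 by edgeR) and Ccl8 of 1.81 (SE 0.39). Cxcl13 had 2.33 (SE 0.719), which rested on P60: its log2 ratios were -0.03, 0.58, 0.57 and 3.74 from P4 to P60, with at most 1 count per library at P4 and P14, and without the P60 pair it had 0.64. Macrophage genes had a camera BH of 0.0021 (adjusted p = 0.728 with an estimated correlation), with Ctss at 1.27, Cx3cr1 at 0.82 and Cd68 at 0.66. The macrophage median log2 ratio was -0.14 at P4, 0.55 at P14, 0.23 at P30 and 0.86 at P60. The lipid-associated macrophage list, with Trem2 at 1.25, had a camera BH of 0.0238 (adjusted p = 0.614 with an estimated correlation). Interferon-stimulated and MHC class I genes each had a camera BH of 0.0412 (adjusted p = 0.614 and 0.585 with an estimated correlation). Over all genes edgeR called 0 in each of these 5 lists, in the order above with 5, 11, 4, 13 and 2 at an unadjusted p below 0.05, DESeq2 called 3, 2, 3, 2 and 1, and limma-trend 1, 0, 0, 1 and 0. When adjusted over the list alone, 3, 0, 0, 1 and 1 passed. Without the P60 pair the macrophage lists had adjusted p of 0.156 and 0.201, and MHC class I 0.187, while without P4 MHC class I had 0.0959. The interferon list had 0.0623 without P14 and 0.236 without P30.

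Genes of myelin and lipid synthesis ranked lower in Seh1cKO. For 20 myelin protein genes the median log2 fold change was -0.28 and the camera BH 3.2e-06 (adjusted p = 0.585 with an estimated correlation). The median log2 ratio was -0.49 at P4 and -0.36 at P14, while -0.10 at P30 and -0.22 at P60 lay within the central 95% of random lists. Over all genes edgeR called 0, with 9 at an unadjusted p below 0.05, DESeq2 called 7 and limma-trend 0, and 7 passed as lower and 1 as higher when adjusted over the list alone. Mbp and Mal, which encode myelin proteins, had -0.53 and -0.48, and Cntn2 had 0.70. Whole nerve was measured, so a smaller share of Schwann cell RNA was not separated from lower expression of myelin genes. At P14 macrophage and adipocyte medians were 0.55 and 0.89, and endothelial and red blood cell medians -0.18 and -1.81. All 23 cholesterol synthesis genes lay below 0 (median -0.34, camera BH 3.65e-06, adjusted p = 0.614 with an estimated correlation), with 9 at an unadjusted p below 0.05. EdgeR and limma-trend called 0 of them, DESeq2 1, and 0 passed when adjusted over the list alone. Their median log2 ratio was -0.48 at P4, -0.24 at P14, 0.18 at P30 and -0.90 at P60. Tm7sf2, Hmgcs1 and Insig1 had -0.57, -0.51 and -0.51. The myelin lipid list had a camera BH of 0.00709 (adjusted p = 0.614 with an estimated correlation) and 0.0706 without the P14 pair. Its median log2 ratio was -0.30, -0.33, 0.13 and -0.31 from P4 to P60. Of its 16 genes edgeR called 0 over all genes, with 7 at an unadjusted p below 0.05, DESeq2 5 and limma-trend 0. Adjusted over the list alone, 6 passed as lower and 1 as higher, and Scd2, Elovl6, Scd1 and Cers2 had -0.65, -0.61, -0.59 and -0.50.

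Neuronal transcripts ranked higher (10 of 10 above 0, median 0.66, camera BH 1.83e-05, adjusted p = 0.585 with an estimated correlation). Over all genes edgeR called 1, Calca, with 8 at an unadjusted p below 0.05, DESeq2 called 7 and limma-trend 1, and 8 passed when adjusted over the list alone. The median log2 ratio was 0.56 at P4, 1.08 at P14 and 0.81 at P60, but 0.15 at P30, within the central 95% of random lists. There 6 of 10 were higher, and Syt1 and Tubb3, chosen after their values were seen, had -1.32 and -0.92. Snap25, Rbfox3 and Nefm had log2 fold changes of 0.80, 0.77 and 0.70. The skeletal muscle list ranked lower (camera BH 0.0412, adjusted p = 0.751 with an estimated correlation). Of its 18 genes edgeR, DESeq2 and limma-trend called 0, with 2 at an unadjusted p below 0.05 by edgeR. Its median log2 ratio was -3.28 at P4 and 1.77 at P30, and its adjusted p was 0.807 without P4, 0.0696 without P14 and 0.0757 without P60. Medians lay within the central 95% of random lists at P4, P14 and P30 for chemokines and MHC class I, at P4 and P14 for p53 targets, at P4 and P60 for DNA damage and interferon genes, and at P4 and P30 for lipid-associated macrophages. Over all lists and ages 76 of 148 medians lay outside it. Swapping genotype labels within ages gave 6 to 14 called lists in the other splits that part all 4 pairs, against 14 with the real labels, so 1 other split gave as many.

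**Figure D3:**
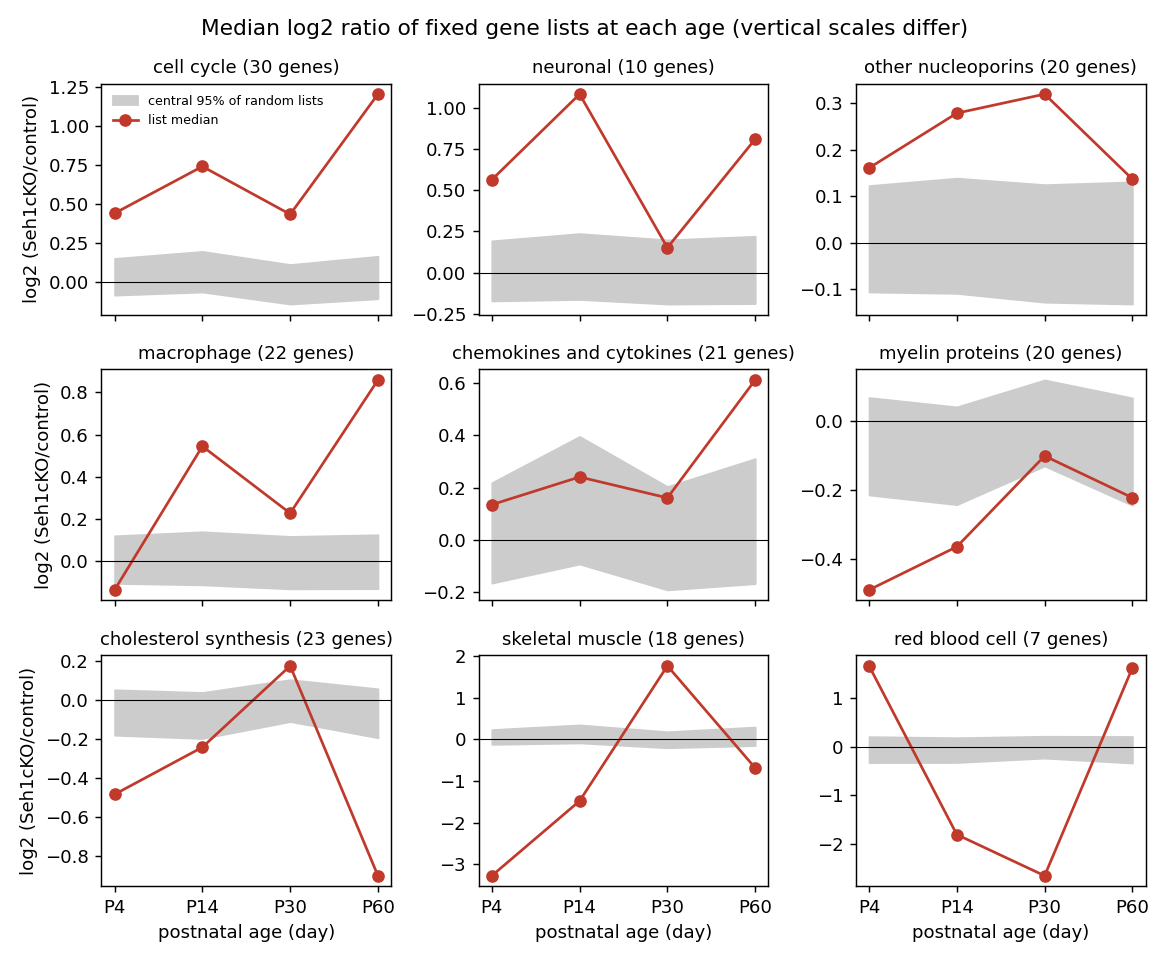
Median log2 ratio of Seh1cKO to control (vertical axes, scales differ) for 9 fixed lists at 4 evenly spaced ages, with the central 95% of 10000 random lists in grey. Cell cycle medians lie above the grey band at each age, from 0.43 to 1.20, and red blood cell medians run from -2.66 to 1.67.

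The remaining lists were not called. Camera BH values were 0.0589 for mast cells, 0.0838 for immediate early genes, 0.102 for the unfolded protein response, 0.276 for complement, 0.288 for MHC class II, 0.339 for T and NK cells, 0.339 for adipocytes and 0.365 for immature and repair Schwann cells. They were 0.522 for red blood cells, 0.681 for B cells, 0.696 for sex-specific transcripts, 0.713 for neutrophils and 0.815 for the integrated stress response. Promyelinating transcription factors, fibroblasts, perineurial cells, endothelial cells, and pericytes and smooth muscle each had 0.631. Median, mean and test differed in sign for complement (median 0.15, mean -0.54, tested as higher), whose mean rested on the fitted value of C2 (-9.21), a gene with 0 counts in Seh1cKO and a value set by the prior count. They also differed for B cells (-0.22 and 0.20, tested as lower). Neutrophils (0.03 and 0.07) and promyelinating factors (0.00 and 0.02) were tested as lower.

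At single ages the libraries of a pair were compared without a test. At P4, 77 of 11531 genes were at least 2-fold higher in Seh1cKO and 71 at least 2-fold lower. These counts were 272 and 106 of 11971 at P14, 90 and 162 of 11719 at P30, and 301 and 212 of 11891 at P60. Across genes, which are not independent replicates, log2 ratios at P4 and P30 had a Pearson's r of -0.00623, and those at P14 and P60 of 0.239, the lowest and highest of 6 pairs of ages.

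At P4 the muscle genes Myh4 (ratio 0.0236), Mybpc2, Atp1b4, Cmya5, Actn2, Myh8, Myom2 and Atp2a1 had the lowest ratios, in the pair whose muscle share was 0.013% and 0.126%. Rnf8 (5.3), Kpna2 (4.46), Zbed5, Zfp493, Cnbd2 and Gemin5 were high. Hba-a1 (3.51) shares reads with a near-identical copy and is uncertain. Pax6os1, an antisense transcript whose reads cannot be told from those of its partner, had 0 control counts and 407 in Seh1cKO at P4, 492 at P14 and 652 at P30, or at least 128-fold, 152-fold and 211-fold higher, but at P60 it had 2.68 CPM in control and 0 counts in Seh1cKO.

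At P14 the brown fat genes Cidea, Ucp1 (4.77) and Cox8b, with Ahcy (7.6), Cxcl10 (7.39) and Snhg11, were high, and the adipocyte list median was 0.89. Ddx3y, Rsbn1, Atp5g2, Rxrg (0.105), Adgb (0.139), Fads6 (0.149), the tight junction gene Cldn11 (0.159) and the oxytocin receptor gene Oxtr (0.185) were low. At P30 Cxcl14 (10.9), the neuregulin gene Nrg1 (7.95), the matrix gene Tnc (6.51) and the muscle genes Myh4, Mybpc2, Atp2a1 and Ampd1 were high. Mmd2 (0.0136), Lrrc4c (0.064), Rxrg (0.0663), the glutamate receptor gene Grik3 (0.0767), Adgb, Cldn11 and the potassium channel gene Kcnh2 (0.113) were low. Entpd4b, whose reads can be shared with a near-identical gene, had 192 control counts and 0 in Seh1cKO at P30, but 26 and 222 at P14.

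At P60 Gdnf, a trophic factor gene, had a ratio of 33.2 (counting interval 15 to 91.6), and the signalling gene Shh of 23.5 (14.3 to 41.5). The cytokine gene Clcf1 (11.7), the chemokine gene Cxcl13 (13.8) and Chil3 were also high, as was Tyrp1 (2 control counts, interval 30.4 to 922). Cnmd (0.047), Cadm2 (0.0599), Mmd2, Lrrc4c, Adgb, Them5, Clvs1 and Luzp2 were low. The neutrophil, macrophage, endothelial and adipocyte list medians at P60 were 1.82, 0.86, 0.68 and 1.01.

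In the immature and repair Schwann cell list, Id2 rose and Gpr37l1 fell across ages, and other members lay far apart. Gdnf had log2 ratios of 0.45, 1.94, 3.64 and 4.65 from P4 to P60, with 1 control count at P30 (ratio without prior count 34.9, interval 5.88 to 1420). Gfap had -0.05, -1.90, -4.09 and -3.81, with 1 count in Seh1cKO at P30 (ratio without prior count 0.0202, interval 0.000501 to 0.118). Ncam1, L1cam and Cdh2, adhesion genes chosen after their values were seen, had ratios of 1.33, 1.1 and 0.943 at P4, 0.225, 0.168 and 0.189 at P30, and 0.219, 0.324 and 0.275 at P60.

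**Figure D4:**
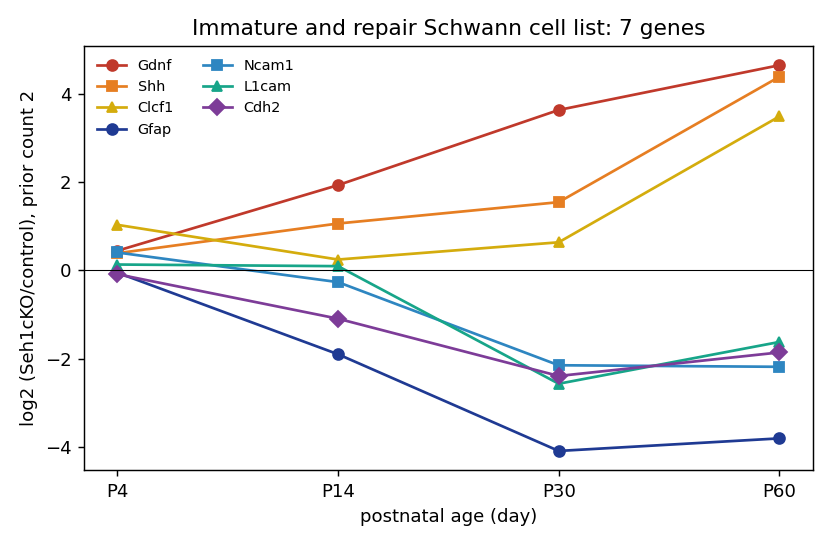
Log2 ratio of Seh1cKO to control with a prior count of 2 (vertical axis) for 7 genes of the immature and repair Schwann cell list at 4 evenly spaced ages, with 1 pair of libraries per point. Gdnf reaches 4.65 at P60 and Gfap lies at -4.09 at P30.

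The test of a genotype difference that changed with age called 0 of 15839 genes (lowest BH 0.207, edgeR quasi-likelihood test), with 1441 genes at an unadjusted p below 0.05. Limma-trend called 0 and DESeq2 123. Without the P14 pair edgeR called 65, without P60 47, without P4 3 and without P30 2. The 8 genes of lowest p, none past the threshold, were Pax6os1, Slc9a3, Cx3cr1, Tuba1b, Lgr6, Ptn, Dhrs2 and Sumo2. Cx3cr1, a macrophage receptor gene, had log2 ratios of -0.41, 0.79, 1.08 and 1.93 from P4 to P60, and the growth factor gene Ptn 0.03, -0.63, -1.22 and -1.44.

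The comparison of P60 with P4 asked how the nerve changed postnatally. The adipocyte genes Cfd and Retn rose from 0.908 to 807 CPM and from 0.173 to 76.5 CPM (BH 0.000102 and 3.17e-05, edgeR). Cyp2e1, with 2 and 1 counts at P4, rose from 0.0752 to 537 CPM. The carboxylesterase genes Ces1d and Ces1f had 0 counts in both P4 libraries and were at least 506-fold and 125-fold higher, against a floor of 3 counts in each library. Retnla, Inmt, Myoc, Pla2g5 and Plk5 also rose. Adipocyte genes took 0.00455% of counts in Seh1cKO and 0.00558% in control at P4, and 0.343% and 0.16% at P60. A changed share of fat or other tissue in the samples was not separated from change within cells of the nerve. The AMPA receptor gene Gria2 fell (log2 fold change -6.19, SE 0.193, BH 3.17e-05 by edgeR), as did Agtr2 (-5.56), Dlk1 (-5.25), Prnd, the fibrillin gene Fbn2 (-5.15), Dab1, Troap, Depdc1a and Neil3. Myh8, a developmental myosin, had 0 counts at P60 and was at least 748-fold lower, though its P4 counts were 4208 in control and 307 in Seh1cKO.

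In all 7506 genes were called, 3764 higher and 3742 lower at P60. All 30 cell cycle genes fell (median log2 fold change -3.57), as did 15 of 20 nucleoporins outside the Y complex and 18 of 26 DNA damage response genes. Among interferon-stimulated genes 32 of 35 rose, as did 20 of 22 macrophage, 10 of 10 adipocyte and 9 of 9 perineurial genes. Of 20 myelin protein genes 4 rose and 7 fell.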

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

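Of the tests in this part, those on library sex, macrophages and a younger state were chosen only after the result was seen. In 10 of 37 lists the median log2 ratio lay below the central 95% of random lists at 1 age and above it at another. These differences between ages were not tested, and lying outside that range was common, as 76 of 148 list medians did.

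The cholesterol synthesis median log2 ratio was 0.177 at P30 and -0.901 at P60. Macrophage medians were -0.135 at P4 and 0.859 at P60. Neutrophil medians were -1.357 at P30 and 1.819 at P60. Perineurial medians were -0.283 at P14 and 0.374 at P30. Endothelial medians were -0.181 at P14 and 0.681 at P60. Skeletal muscle medians were -3.276 at P4 and 1.768 at P30. Adipocyte medians were -0.917 at P4 and 1.011 at P60. Red blood cell medians were 1.668 at P4 and -2.662 at P30. Myelin lipid medians were -0.334 at P14 and 0.131 at P30. Sex-specific medians were -2.019 at P14 and 2.134 at P60.

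The cell cycle median lay above 0 at each age, with 30 of 30 genes higher at P4, P14 and P30 and 28 at P60, though edgeR called 1 of them and the list had adjusted p = 0.457 with an estimated correlation. A difference in sex is argued against at P30, where the sex-specific median was 0.096 and the cell cycle median 0.434, above all 10000 random lists, and so is a sex effect of 1 direction as the whole cause at P14 and P60, where the pairs differed in Y-linked transcripts in opposite directions and the lower cell cycle median was 0.74. Sex stays open at P4, where the sex-specific median was -0.866, as does a sex effect that turns with age. At P4 more macrophages do not account for it, as their median was -0.135. From P14 to P60 dividing macrophages cannot be told apart from dividing Schwann cells or other cells, because whole nerve was measured. The cell cycle and macrophage medians were both highest at P60 (macrophage 0.859). Neutrophil, red blood cell, adipocyte and endothelial medians there were 1.819, 1.626, 1.011 and 0.681, and the fibroblast median was -0.116. A generally younger state may contribute: genes that fell with age had a genotype median only 0.039 above genes that rose, which decides nothing.

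All 23 cholesterol synthesis genes were lower in Seh1cKO than in control at P60, without a test at that age, and across ages the list had adjusted p = 0.614 with an estimated correlation. Dilution of Schwann cell RNA by other cells as the whole cause would lower myelin genes as much. Of 20 myelin protein genes 0 lay at or below the cholesterol median. Dilution as a part of the cause stays open, since 16 of the 20 were lower at P60, with a median of -0.223. A sex effect of 1 direction as the whole cause is argued against by the P14 pair, which differs in Y-linked transcripts the other way round and had a median of -0.241, with 22 of 23 genes lower. A sex effect that turns with age stays open. A genotype effect on this pathway remains a hypothesis, and at P30 the median was 0.177, with 22 of 23 genes higher in Seh1cKO.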

How the results depend on the processing

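The fits with library sex, muscle level or blood level, on the P4 and P30 pairs, and on log2(FPKM + 1) were chosen only after the data were seen. Counts for P60 against P4 stayed within 1.5 times in each fit run, and it cannot be made without P4 or P60. RLE scaling moved no count beyond 1.5 times. The cause of the changes below was not tested. A pseudocount of 0.1 and the other settings meant for FPKM or TPM were not run, since counts were tested. Library size scaling moved the median of all genes by 0.071, and by 0.132 at P14.

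Genes higher and lower by genotype, 13 and 37, became 7 and 13 with library size only, 39 and 106 without a filter, 30 and 67 at 5 CPM in 4 libraries, 344 and 546 with DESeq2, and 34 and 76 with limma-trend. With edgeR they were 0 and 0 without an age term, with a line in log2 day and in the P4 and P30 pairs, where 467, 1540 and 896 genes had an unadjusted p below 0.05. They were 0 and 3 with sex, 0 and 1 with blood, and 5 and 3 on log2(FPKM + 1), and 79 were lower with muscle. With each pair left out they ranged from 0 to 56 and from 0 to 121. For the change with age, DESeq2 gave 62 rising and 61 falling genes, no filter 1 falling, and left-out pairs 1 to 30 rising and 1 to 35 falling. Wdr24 turned to -0.058 in the P4 and P30 pairs and Mios to 0.009 on log2(FPKM + 1), and Wdr59 ranged from -0.154 to 0.026 with pairs left out.

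At single ages, higher and lower genes at a minimum of 1 CPM were 196 and 202 at P4, 601 and 212 at P14, 248 and 320 at P30, and 616 and 364 at P60. At 20 CPM they were 26 and 32, 80 and 45, 34 and 78, and 117 and 102. With library size only, 433 were higher at P14.

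Lists higher and lower, 10 and 4, were 0 and 0 with an estimated correlation and 4 and 2 with fry, and 2 were lower in the P4 and P30 pairs. Adjusted p with an estimated correlation was 0.457 for cell cycle, other nucleoporins, p53, DNA damage and chemokines, 0.585 for myelin proteins, MHC class I and neuronal genes, 0.614 for cholesterol, interferon, lipid-associated macrophage and myelin lipid genes, 0.728 for macrophages and 0.751 for muscle. Fry, which does not compare a list with other genes, gave 0.118 for myelin proteins and neuronal genes, 0.373 for cholesterol, 0.0522 for p53 and DNA damage, 0.269 for interferon and myelin lipid genes, 0.0567 for chemokines, 0.214 for MHC class I, 0.393 for macrophages, 0.255 for lipid-associated macrophages and 0.718 for muscle. It called other nucleoporins and the Y complex (0.0326), cell cycle (0.0387) and the unfolded protein response (0.00607) as higher. Mast cells (0.0326) and GATOR2 (0.0387) were called as lower. The GATOR2 list holds the knockout target Seh1l, with a log2 fold change of -0.89. Its other members Mios, Wdr59, Wdr24 and Sec13 had -0.10, -0.07, 0.05 and 0.05. The GATOR2 call thus rests largely on the target, and fry was not run without it. Library size only gave 0.0974 for interferon and 0.0178 for mast cells, and the sex term 0.0506 for muscle.

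In the P4 and P30 pairs adjusted p was 0.0566 for cholesterol, 0.0509 for p53, 0.075 for chemokines, 0.239 for MHC class I, 0.5 for macrophages, 0.366 for lipid-associated macrophages, 0.145 for muscle and 0.36 for myelin lipid genes. It was 0.0129 for neutrophils and fibroblasts and 0.0034 for perineurial cells. Direction turned for promyelinating factors (0.609), the integrated stress response (0.866), endothelial cells (0.293) and adipocytes (0.293).

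With pairs left out, adjusted p ranged from 0.00281 to 0.0787 for p53, 0.00408 to 0.236 for interferon, 0.0234 to 0.189 for DNA and RNA sensing, 0.0232 to 0.187 for MHC class I, 0.0267 to 0.578 for MHC class II, 0.554 to 0.79 for the integrated stress response, 9.82e-06 to 0.156 for macrophages and 0.0142 to 0.201 for lipid-associated macrophages. It ranged from 0.101 to 0.924 for T and NK cells, 0.0302 to 0.882 for neutrophils, 0.0335 to 0.0959 for mast cells, 0.189 to 0.955 for fibroblasts, 0.0331 to 0.937 for perineurial cells and 0.0925 to 0.656 for endothelial cells. For muscle it ranged from 5.32e-07 to 0.807, for adipocytes 0.00241 to 0.917, for red blood cells 0.0931 to 0.936, for myelin lipid genes 4.65e-05 to 0.0706, for sex-specific transcripts 0.0267 to 0.937 and for immediate early genes 0.0257 to 0.274. Direction turned in at least 1 of these fits for the integrated stress response, T and NK cells, neutrophils, fibroblasts, perineurial cells, endothelial cells, red blood cells and sex-specific transcripts.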

Other observations

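Of the tests in this part, the one on library sex was chosen only after the result was seen.

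The transcription factor genes Junb and Egr1, of the immediate early list, had log2 fold changes of 1.28 and 0.96 (BH 0.0771 and 0.0818 by edgeR). Mcpt4, a mast cell protease gene, had -0.70 (BH 0.0713 by edgeR). In the perineurial list, where 7 of 9 genes lay above 0, the integrin gene Itgb4 had -0.49 (BH 0.0849 by edgeR). EdgeR called none of Junb, Egr1, Mcpt4 and Itgb4 and DESeq2 each, and over 18 alternatives their lowest adjusted p was 7.41e-05, 7.07e-05, 0.0122 and 0.000597 and their highest 1. Of 12 immediate early genes edgeR called 0, with 6 at an unadjusted p below 0.05, DESeq2 4 and limma-trend 0. Of 7 mast cell and 9 perineurial genes edgeR called 0, with 2 in each list at an unadjusted p below 0.05, DESeq2 1 in each and limma-trend 0.

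Gfap, Ncam1, L1cam and Cdh2 had low ratios of Seh1cKO to control at P30 and P60, without a test at these ages. Dilution by other cells as the whole cause would lower myelin genes alike. Of 20 myelin protein genes 0 lay at or below the highest of these genes. A difference in sex is argued against at P30, where the sex-specific median was 0.096 and that of these genes -2.48, and so is a sex effect of 1 direction as the whole cause at P60, since the highest of their log2 ratios was 0.098 at P14, where the pair differed in Y-linked transcripts the other way round, while a sex effect that turns with age stays open. Fewer non-myelinating Schwann cells, or less of their expression programme, may account for it: of another 7 marker genes, fixed before their values were looked at, the higher of the medians at P30 and P60 was -1.626, below all 10000 random lists. Scn7a had -3.02 and -2.14 and Sorcs1 0.17 and -0.20 at these ages, and loss of cells and lower expression were not separated. In the immature and repair list, which holds Gfap, Ncam1, L1cam and Cdh2, 9 of 20 genes were higher at P30 and 14 at P60. Ngfr and Gap43 of that list, chosen after their values were seen, had -0.707 and -0.089 at P30 and 0.435 and 0.414 at P60.

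Other splits of the libraries were too few for a share under 0.05. Of 8 splits that part all 4 age pairs, 1, the real split, gave 50 genes, and the highest other gave 0. For lists, 2 of the 8 gave 14 or more, the real one included, and the highest other gave 14. The 24 splits that part 2 of the pairs, and so leave libraries of 1 age together, gave up to 12 genes and up to 16 lists.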
